A study of Homo sapiens with 12 samples.

How the data were processed

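RNA from A549 cells was sequenced, after an siRNA against SLC7A5 or a scrambled siRNA, in 6 libraries each. Per the labels, libraries were made from mRNA with oligo-dT and read from both ends, and 1 batch label covers all 12 samples. The deposited table gives whole-number counts per feature and library, which were analysed as raw counts. Per the submitters' processing notes, the tools included Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 and the genome build was GRCh38. The notes give no role for each tool. RSEM as a rule gives estimated counts that need not be whole, and how the whole numbers were made is not given in the sources used here, nor is a strand setting. Without it, reads from a gene and its antisense partner cannot be told apart. Row names carry 3 styles, 50342 rows in an NCBI gene style, 2139 in an NCBI transcript style and 5275 in the style of assembled transcripts. A RefSeq gene table (GRCh38.p14) matched the symbols of 57721 of 57756 rows, and 5516 symbols had several rows. For a named gene the row of the gene itself was used.

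Each column was matched to a sample by its name. No row lacked a gene name. Pairs of libraries were compared by a chi-square test over 26023 features with a mean of at least 20 counts. The statistic per degree of freedom had a median of 1.277 over 30 pairs within groups and 1.276 over 36 pairs between groups. It ranged from 1.236 to 1.32 within and from 1.239 to 1.324 between groups, where counting noise alone gives about 1. All libraries thus differed little beyond counting noise, within groups as between them. No pair stood apart, so no library was merged with another. With 1896100 to 2109699 counts per library, the median feature had 16 or 17 counts, which limits the precision for single genes. Intervals cover the spread between libraries as modelled by edgeR.

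The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, TMM normalization, filterByExpr) in R 4.3.3, with group as the single term and Benjamini-Hochberg adjustment at 0.05. CPM were computed from library totals. SLC7A5 was also tested alone with an exact two-sided permutation test. Lists were tested with camera (limma 3.58.1, preset correlation 0.01, and with an estimated correlation) and with fry. DESeq2 1.42.0 and limma voom were alternatives, together with RLE, upper quartile and plain library totals as scaling, no low-count filter, a filter of 1 CPM in 6 libraries, no robust estimation, an adjusted p under 0.01, the replicate number as a block, and each library left out in turn. Design, alternatives and 37 gene lists were fixed before the data were examined. Summing rows by gene symbol was added after seeing the data. Of 1046 list members, 1045 matched a row.

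The rule for named genes, also fixed then, takes SLC7A5, 20 genes of the study question, up to 12 genes per direction past the threshold with a log2 fold change of at least 0.5, and up to 4 members of each list with the smallest adjusted p. As 0 genes passed the size part, the text names 2 members for lists closest to the study question and 1 for the others. Any other gene named was chosen after its values were seen. The result of 1 gene that the rule takes is not reported here.

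The test was tested on simulated data. In 5 simulated tables with the real means and library sizes and 200 changed genes each, it recovered 13.6% of genes changed 1.25-fold, 48% changed 1.5-fold, 82.4% changed 2-fold and 93.2% changed 4-fold, with a mean of 6.4 false calls among 125. Among genes with 40 to 80 counts, the range that holds most SLC7A5 values, it recovered 100% of those changed 2-fold. The changes were made in the counts themselves, so recovery applies to transcripts only where counts track them.

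Exonic length was the union of annotated exons in GENCODE release 29 (GRCh38), joined by symbol and chromosome for 17097 protein-coding genes. Counts per kb are the mean count over the 12 libraries divided by that length. Only classes in which at least 80% of members had a length are shown. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for these steps.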

Results

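The data were gene-level sequencing counts from 12 libraries of A549, an established human lung adenocarcinoma cell line. In 6 libraries the cells had received a scrambled siRNA, which matches no intended transcript, and these are called control. In the other 6 they had received an siRNA against SLC7A5, the light chain of a transporter that carries large neutral amino acids such as leucine into the cell. The series asks which lipid metabolic genes depend on SLC7A5, with PPARA, a nuclear receptor that switches on fatty acid breakdown, named as the link to metastasis. Total counts lay between 1896100 and 2109699 per library, with a mean of 1971700 ± 52614 (SD, n = 6) in control and 1975426 ± 79186 (SD, n = 6) in the knockdown group. The table held 57756 features, of which 53436 ± 184 (SD, n = 6) had at least 1 count in a control library and 53411 ± 219 (SD, n = 6) in a knockdown library. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

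SLC7A5 itself (GRCh38, chromosome 16, 87830023 to 87869507) was not lower in the libraries labelled knockdown. Its level was 27.97 ± 3.34 CPM (counts scaled to the library total; SD, n = 6) in control and 31.47 ± 5.59 CPM (SD, n = 6) in the libraries labelled knockdown. The control libraries held 27.06, 26.23, 27.98, 31.86, 23.09 and 31.56 CPM, and the libraries labelled knockdown held 32.65, 27.97, 27.62, 27.05, 31.64 and 41.87 CPM. The counts behind these values were 45 to 65 in control and 53 to 80 in the libraries labelled knockdown. The fold difference was 1.123 with a 95% interval of 0.947 to 1.331, so a reduction beyond 5.3% lay outside the interval. The exact permutation test over all distinct splits of the 12 libraries gave a two-sided p of 0.1883, and edgeR gave an adjusted p of 0.998. Without knockdown replicate 6 the log2 fold change was 0.07 in place of 0.167. The pseudogenes SLC7A5P1 and SLC7A5P2 are near-identical to parts of SLC7A5 and could share its reads. SLC7A5P1, below the filter in edgeR, had 8 counts over the 6 controls and 24 over the 6 libraries labelled knockdown, of which 10 were in replicate 4. The 2 rows of SLC7A5P2 had 77 and 73 counts over the controls and 92 and 84 over the libraries labelled knockdown. Their counts were the same or close in most libraries, so the 2 rows are not separate evidence. Exact two-sided permutation tests of CPM, chosen after these values were seen, gave p = 0.0087 for SLC7A5P1 (0.026 adjusted over the 3 rows) and p = 0.1797 and 0.3355 for the rows of SLC7A5P2 (0.2695 and 0.3355 adjusted). Because the targeted gene goes against the label, directions below are given for "the libraries labelled knockdown".

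SLC3A2, the heavy chain that pairs with SLC7A5 at the cell surface, stood at 14.04 ± 1.2 CPM in control and 15.87 ± 3.82 CPM in the libraries labelled knockdown (SD, n = 6 each). PPARA stood at 73.87 ± 6.68 and 74.94 ± 8.5 CPM (SD, n = 6 each), a log2 fold change of 0.02 with a standard error of 0.08. CPT1A, which admits long-chain fatty acids to mitochondria for oxidation, stood at 45.24 ± 7.34 and 40 ± 4.26 CPM (SD, n = 6 each), a log2 fold change of -0.18 with a standard error of 0.105. CDH1, the epithelial adhesion protein E-cadherin, stood at 29.19 ± 4.43 and 32.77 ± 5.16 CPM (SD, n = 6 each). Each of these genes had an adjusted p of 0.998 in edgeR.

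**Figure D1:**
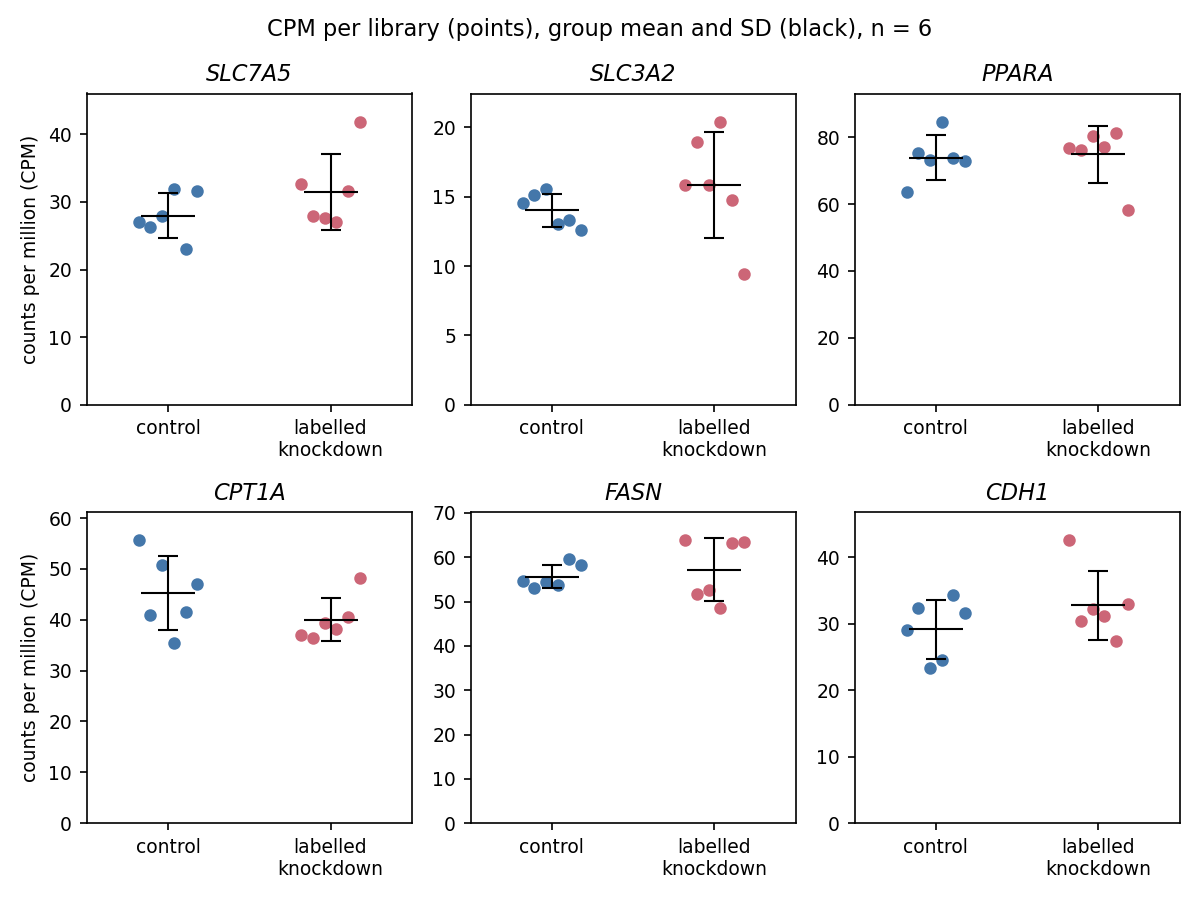
CPM (y axis, from 0) of 6 genes in each library, with 1 point per library, the group mean as a black line and the SD as bars (n = 6 per group). SLC7A5 averages 27.97 CPM in control and 31.47 CPM in the libraries labelled knockdown, and the groups overlap in each of the 6 genes.

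Across the transcriptome, edgeR's quasi-likelihood test called 0 of 35754 genes higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.933. At an unadjusted p under 0.05 there were 828 genes higher and 810 lower, 1638 together, where chance alone gives 1788. DESeq2 called 0 genes higher and 1 lower, ZFP91-CNTF. Run without the low-count filter, it had 1104 of 57010 features at an unadjusted p under 0.05, where chance gives 2850 if p-values are uniform. That need not hold for features with few counts, so this share is not comparable with the filtered fits. The limma voom fit called 1 gene higher, CNTF, and 0 lower, with 1736 of 35754 genes at an unadjusted p under 0.05, where chance gives 1788. The median absolute log2 fold change was 0.097, and the 95% interval excluded a 2-fold difference for 97.9% of genes. All 6 libraries labelled knockdown lay above or below all 6 controls for 66 genes, or 0.185% of those tested, against 0.216% by chance. On simulated counts of the same depth, the test recovered 82.4% of genes changed 2-fold and 48% of genes changed 1.5-fold. The simulation changed the counts themselves. The intervals and the recovery thus apply to transcripts only where counts track transcript level, which the values on exonic length below leave in doubt. No principal component separated the groups, the smallest adjusted exact permutation p over the components being 0.6096.

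The genes of lipid metabolism gave 0 calls in edgeR. Of 45 measured PPARA target genes, 18 had positive and 27 negative log2 fold changes, with a median of -0.04. The members with the smallest p were UCP2, a mitochondrial carrier, at 12.19 ± 2.68 CPM in control and 16.92 ± 2.49 CPM in the libraries labelled knockdown, and PEX11A, a peroxisome division factor, at 16.33 ± 1.07 and 21.2 ± 4.56 CPM (SD, n = 6 each). PDK4 stood at 24.54 ± 2.99 and 21.66 ± 4.16 CPM, and ANGPTL4 at 12.5 ± 1.61 and 14.53 ± 1.48 CPM. PLIN2, a lipid droplet coat protein, stood at 15.51 ± 4.08 and 14.84 ± 5.38 CPM. The 45 genes of fatty acid oxidation had a median log2 fold change of -0.02, with HSD17B4 at 0.375 and ACOX2 at 0.33. The 32 genes of fatty acid synthesis and desaturation had a median of -0.03, with ELOVL2 at -0.107 and ACACB at -0.114. FASN, the fatty acid synthase, stood at 55.6 ± 2.65 and 57.21 ± 7.01 CPM, and SCD, a desaturase, at 33.51 ± 5.41 and 32.93 ± 3.19 CPM. Cholesterol synthesis and uptake (25 genes) had a median of -0.03, with ACAT2 at 0.793 and SREBF2 at 0.169. ACAT2 had 0 counts in control replicate 5, and its log2 fold change was 0.538 without that library and 1.317 in limma voom. Lipid uptake, storage and lipolysis (41 genes) had a median of -0.01, with FITM2 at -0.343 and MGLL at 0.305. The PPAR receptors and coregulators (15 genes) had a median of 0.004. PPARG stood at 46.15 ± 6.13 and 41.76 ± 3.73 CPM, PPARD at 52.18 ± 8.01 and 55.03 ± 4.58 CPM, and EP300 had a log2 fold change of 0.11.

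Genes tied to amino acid supply also gave 0 calls in edgeR. The 32 amino acid transporters had a median log2 fold change of 0.02, with 18 positive and 14 negative. SLC7A8, the other light chain of the same transport system, stood at 32.31 ± 5.26 CPM in control and 30.92 ± 5.48 CPM in the libraries labelled knockdown. SLC7A11, a cystine carrier, stood at 78.37 ± 11.3 and 77.61 ± 7.89 CPM, and SLC1A5, a glutamine carrier, at 21.47 ± 5.99 and 20.99 ± 4.32 CPM (SD, n = 6 each). SLC1A1 had a log2 fold change of 0.232 and SLC1A4 of -0.207. The 38 genes of the ATF4 amino acid response, which cells use when amino acids run short, had a median of 0.004 with 19 positive and 19 negative. ATF4 stood at 13.06 ± 2.87 and 12.4 ± 1.53 CPM, ASNS at 18.65 ± 3.5 and 21.97 ± 4.15 CPM, PHGDH at 34.79 ± 3.75 and 40.65 ± 2.33 CPM, and PCK2 had a log2 fold change of 0.328. The 19 measured cytosolic aminoacyl-tRNA synthetases had a median of 0.03, with WARS1 at 0.346 and RARS1 at 0.373. Branched-chain and aromatic amino acid catabolism (31 genes) had a median of 0.01, with HPD at 0.524 and PPM1K at -0.139. The 38 mTORC1 pathway components had a median of -0.02, with DEPDC5 at 0.181 and RPS6KB1 at 0.213.

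Lists on cell identity and invasion were likewise without calls. The 27 epithelial markers had a median log2 fold change of -0.01, with CRB3 at 0.414 and TJP3 at -0.208. The 27 mesenchymal markers had a median of -0.069, with 10 positive and 17 negative, and fry gave an adjusted p of 0.153 for them. VIM, the intermediate filament vimentin, stood at 14.49 ± 4.36 CPM in control and 13.54 ± 3.04 CPM in the libraries labelled knockdown, ACTA2 at 12.04 ± 1.78 and 9.34 ± 1.66 CPM, and CDH2 at 32.5 ± 5.04 and 28.25 ± 3.88 CPM (SD, n = 6 each). Extracellular proteolysis and invasion (32 genes) had a median of -0.03, with MMP13 at 0.403 and MMP24 at 0.205. Integrins and focal adhesion (33 genes) had a median of -0.001, with TLN2 at -0.138 and ITGA6 at 0.182. The medians were -0.029 for TGF-beta and YAP responsive genes, where CCN1 was at -0.338, and -0.024 for alveolar type II and club cell markers, where CYP2F1 was at 0.374. Markers of other cell types had medians of -0.074 (fibroblast, with PDGFRB at 0.202), -0.008 (leukocyte, with MS4A1 at 0.418) and 0.026 (endothelial, with ROBO4 at -0.213).

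Growth, stress and housekeeping lists completed the set. MKI67, a marker of dividing cells, stood at 85.73 ± 5.95 CPM in control and 85.71 ± 7.09 CPM in the libraries labelled knockdown (SD, n = 6 each). The median log2 fold change was -0.003 for the mitotic cell cycle list, with PLK1 at -0.228, and 0.031 for DNA replication, with RRM2 at 0.273. IFIT1, an interferon-induced gene, stood at 31.66 ± 4.8 and 31.56 ± 4.38 CPM, and interferon-stimulated genes had a median of -0.015, with PARP9 at -0.234. The medians were -0.048 for NF-kB and inflammatory cytokines (IL6 at -0.308), 0.004 for p53 targets (TRIAP1 at 0.456), 0.039 for NRF2 targets (CBR1 at 0.304) and -0.017 for glycolysis (PFKFB4 at -0.18). They were 0.001 for lysosome and autophagy (GPNMB at -0.375), 0.021 for the unfolded protein response (SEL1L at -0.242) and -0.026 for immediate early and heat shock genes (JUN at -0.275). They were 0.053 for the nuclear-encoded respiratory chain (UQCRB at -0.172), -0.036 for mitochondrially encoded mRNAs (ND6 at -0.456) and 0.006 for MYC targets and ribosome biogenesis (WDR43 at -0.309). They were 0.035 for cytosolic ribosomal proteins (RPL8 at -0.353), 0.111 for replication-dependent histones (H2BC21 at -0.342) and -0.034 for the small RNA silencing machinery (AGO2 at -0.09). Ribosomal protein and histone genes have near-identical copies, so their counts are uncertain. In the hypoxia response list (median 0.025), EGLN3, an oxygen-sensing hydroxylase, stood at 23.11 ± 3.57 and 15.52 ± 4.36 CPM (SD, n = 6 each). Its adjusted p in edgeR was 0.998 over all genes and 0.0226 adjusted over the list alone.

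Over the 37 lists together, 917 distinct members were tested with edgeR, 0 passed and 34 had an unadjusted p under 0.05. Adjusted over the list alone, EGLN3 was the 1 member to pass in any list. The camera test called 0 lists, with a smallest adjusted p of 0.949, and with an estimated correlation it called 0, with a smallest adjusted p of 0.946. The fry test called 0 lists in a single direction (smallest adjusted p 0.153) and 0 in either direction (0.0963, cholesterol synthesis and uptake). Leaving out SLC7A5, whose shift is given above, 51 named genes had an absolute log2 fold change of at least 0.15. Another setting moved the value of 12 of them by over 1.5 times. Besides ACAT2, these were CPT1A (-0.112) and SLC1A4 (-0.125) without control replicate 1, CDH1 (0.076) and CRB3 (0.25) without knockdown replicate 1, and SLC1A1 (0.122) without knockdown replicate 3. Without knockdown replicate 6 the values were -0.077 for PDK4, -0.144 for PLK1, -0.235 for ND6 and 0.292 for SLC3A2, which stood at 0.102 without knockdown replicate 4 and at 0.183 with all libraries. Without control replicate 3 the values were -0.175 for RPL8 and 0.111 for CDH1, and without control replicate 6 the value of UQCRB was -0.113. In 10 lists the median, the mean and the direction of the camera test differed in sign, PPARA targets and hypoxia response among them. In a simulated table, the counts of the PPARA targets were lowered 1.1-fold. There camera gave that list an adjusted p of 1.3e-05, against 0.0148 with an estimated correlation and 0.00909 with fry. In that single draw, genes varied independently of each other and all members were lowered alike. A real fall of that size could thus be missed.

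**Figure D2:**
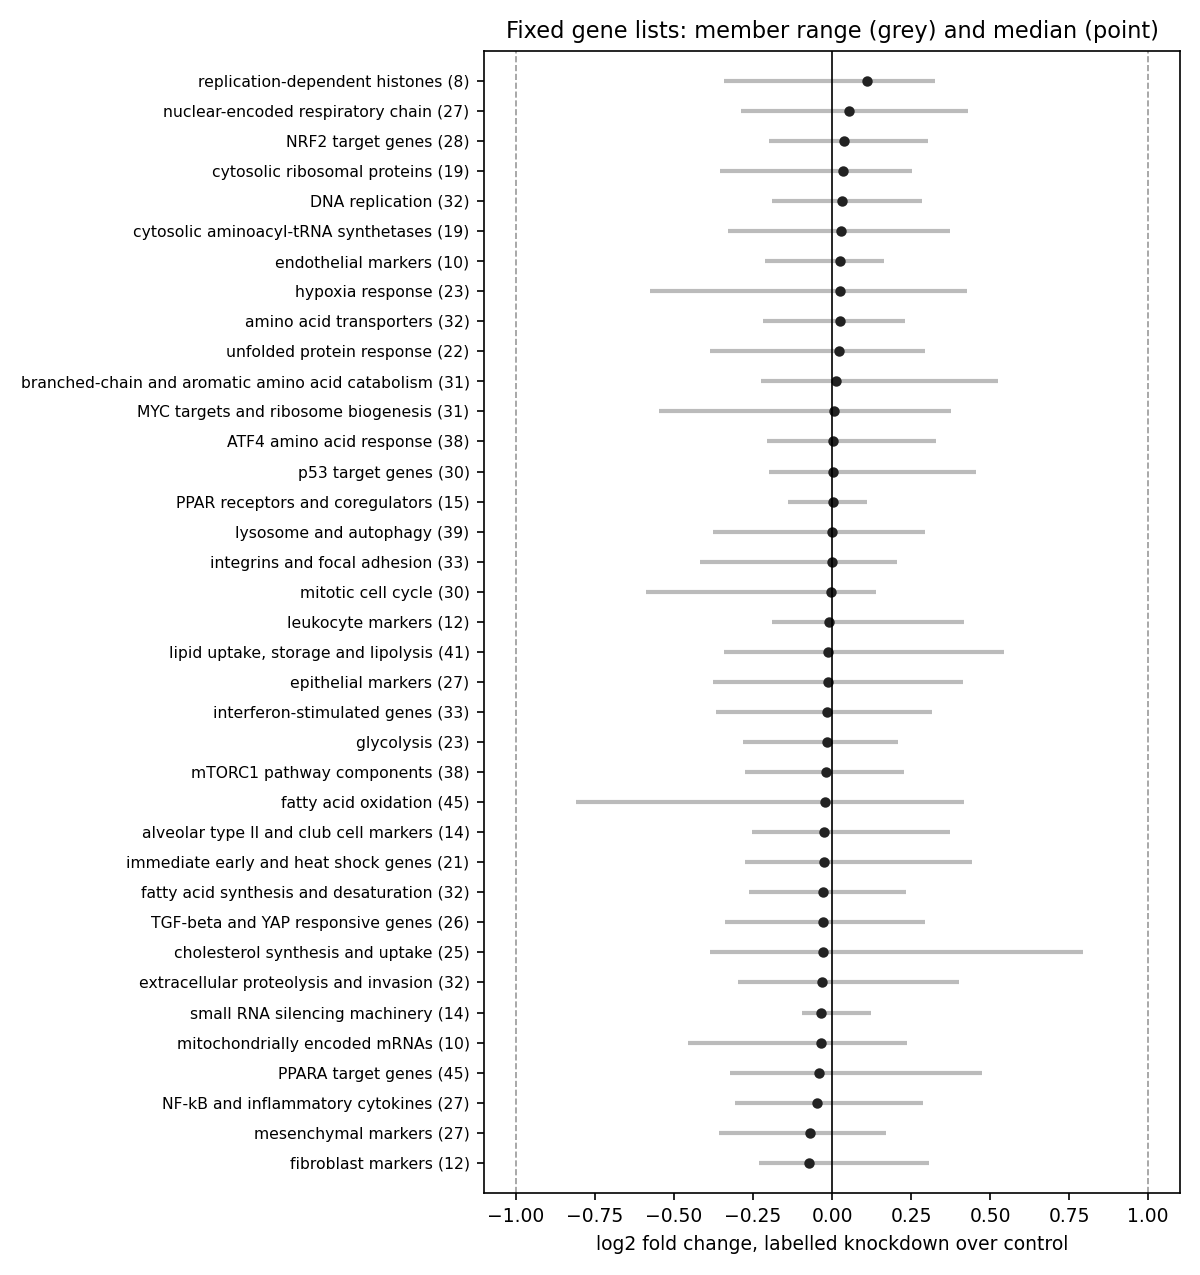
Log2 fold change of the libraries labelled knockdown over control (x axis) for 37 gene lists, with the number of tested members in brackets, the range of members as a grey line and the median as a point. List medians lie between -0.074 and 0.111, and no member range reaches a 2-fold difference (dashed lines).

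Counts followed the annotated length of a gene. Over 17097 protein-coding genes, the mean count correlated with annotated exonic length with a Spearman's rho of 0.801 across genes, which are not independent replicates. The median was 11.73 counts per kb of exon, and 90% of genes lay between 4.81 and 27.51 counts per kb. Olfactory receptor genes, which are used mainly in the nose, had a median of 12.9 counts per kb over 301 genes, and all of them had a count in every library. Cytosolic ribosomal protein genes, which cells transcribe heavily and whose near-identical copies make their counts uncertain, had a median of 4.53 counts per kb over 31 genes. Mitochondrially encoded genes had a median of 15.3 counts per kb over 13 genes. The following genes were chosen after their values were seen. IMMP2L at 508.87, TRMT11 at 269.55 and SETBP1 at 121.55 counts per kb lay far above the median, as did 36 protein-coding genes in all at more than 10 times it, and 124 lay below 0.1 of it. GAPDH, a glycolytic enzyme, held 21 ± 5.6 counts in control and 21.8 ± 9.4 counts in the libraries labelled knockdown, and ACTB, cytoplasmic actin, held 22.5 ± 7 and 22.7 ± 8.4 counts (SD, n = 6 each). ALB, the liver's serum albumin, held 30.2 ± 5.9 and 30.3 ± 7.6 counts, OR4F5, an olfactory receptor, 31.2 ± 3.7 and 31 ± 3.6 counts, and CDKN2A, a gene deleted in A549, 37.7 ± 7.1 and 35.8 ± 6.7 counts (SD, n = 6 each).

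**Figure D3:**
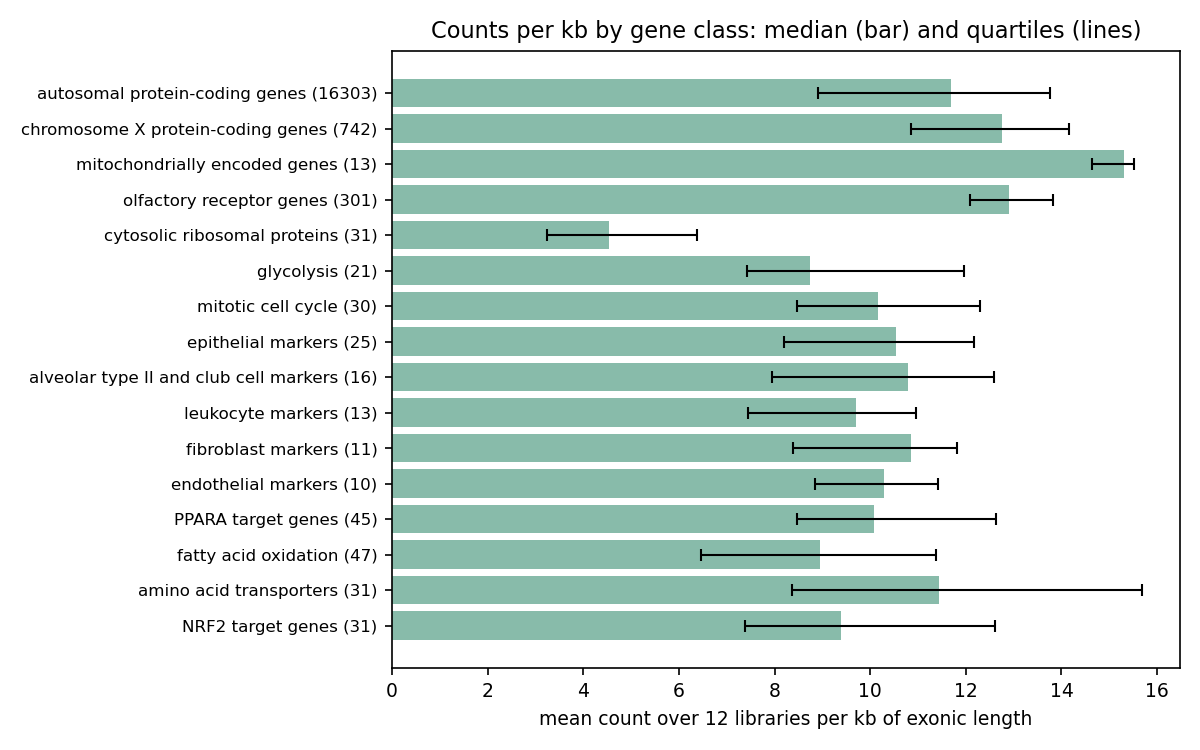
Mean count over the 12 libraries per kb of exonic length (x axis, from 0) for classes of protein-coding genes, with the number of genes in brackets, the median as a bar and the quartiles as lines. Olfactory receptor genes have a median of 12.9 counts per kb and cytosolic ribosomal protein genes 4.53.

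The genes called by the other tools belong to 1 locus on chromosome 11 and were singled out after their values were seen. CNTF (58622665 to 58625733), a neurotrophic cytokine, lies within the annotated readthrough gene ZFP91-CNTF (58579114 to 58625733), so reads from the overlap are uncertain. CNTF had 22 to 35 counts in the 6 libraries labelled knockdown, 20 counts in control replicate 4 and 0 counts in the other 5 controls. ZFP91-CNTF had 0 counts in control replicate 4 and in all 6 libraries labelled knockdown, and 26 to 33 counts in the other 5 controls. With a floor of 3 counts over the group, the pooled counts of ZFP91-CNTF were 51.4-fold lower in the libraries labelled knockdown. This ratio leaves out the spread between libraries. The sum of both features was 29 ± 5.1 counts in control and 26.8 ± 4.6 counts in the libraries labelled knockdown (SD, n = 6 each). In edgeR, CNTF had an adjusted p of 0.998 and ZFP91-CNTF was removed by the filter. The adjusted p was 0.00124 for CNTF in limma voom and 0.00733 for ZFP91-CNTF in DESeq2. Without control replicate 4, edgeR gave adjusted p of 2.57e-08 for CNTF and 7.18e-09 for ZFP91-CNTF.

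**Figure D4:**
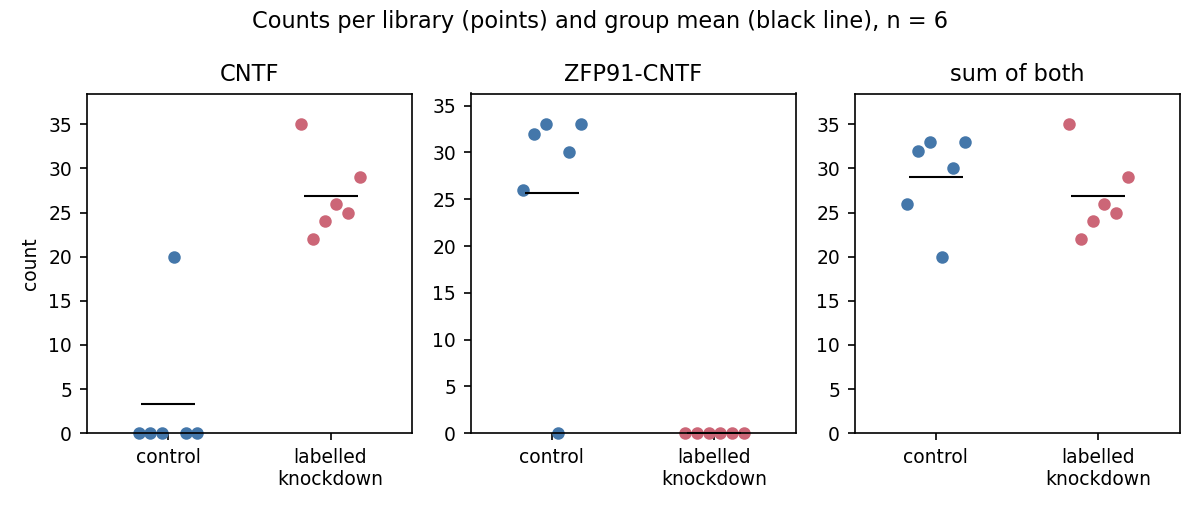
Counts (y axis, from 0) of CNTF, ZFP91-CNTF and their sum in each library, with 1 point per library and the group mean as a black line (n = 6 per group). In each of the 12 libraries only 1 of the features has counts, and the sum averages 29 counts in control and 26.8 in the libraries labelled knockdown.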

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

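Tests in this part on CNTF and ZFP91-CNTF were chosen after the result was seen. In each group of 6 libraries, the highest and lowest values of each named gene and of the totals were compared with their nearest neighbour, 152 groups in all. A gap that is large for the range of the group was found 12 times, where chance gives about 7.6.

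In control, ACAT2 had 0 CPM in replicate 5 against 6.05 to 8.81 in the others. PFKFB4 had 49.53 CPM in replicate 6 (others 41.05 to 43.35), PHGDH 41.96 CPM in replicate 3 (others 31.56 to 34.99), VIM 22.55 CPM in replicate 1 (others 10.45 to 14.88) and WDR43 32.33 CPM in replicate 5 (others 21.19 to 24.28). In the libraries labelled knockdown, replicate 6 had 48.15 CPM of CPT1A (others 36.5 to 40.61), 13.61 CPM of PDK4 (others 21.33 to 25.07) and 58.1 CPM of PPARA (others 76.31 to 81.22). AGO2 had 126.58 CPM in replicate 5 (others 107.12 to 112.03) and CDH1 42.54 CPM in replicate 1 (others 27.42 to 32.98).

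Control replicate 4 stood apart at the CNTF locus, with 20 counts of CNTF where the other controls had 0, and 0 counts of ZFP91-CNTF where they had 26 to 33. In 12 of 12 libraries only 1 of the overlapping features had counts, so a candidate explanation is that the counting step gave the reads of 1 locus to either feature. The summed counts of both features differed by a log2 fold change of -0.109 (95% interval -0.443 to 0.224, exact permutation p 0.476). This argues against a large difference in the counts of the locus as a whole. A rise of CNTF with an equal fall of ZFP91-CNTF would leave the sum unchanged, so it cannot decide the level of CNTF transcript. Among 181 features with 0 counts in some libraries and at least 10 in all others, the 2 at this locus differed by 5 or more libraries between the groups. They mirror each other and so count as 1 event, singled out after it was seen, and chance is not excluded as the reason that the switch follows the group in 11 of 12 libraries.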

How the results depend on the processing

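The added summing of rows by symbol was chosen after the data were seen. DESeq2 called 1 gene lower and 1 gene changed at least 2-fold, ZFP91-CNTF, and limma voom called 1 gene higher and 1 changed at least 2-fold, CNTF. Leaving out each library in turn gave 0 to 1 genes higher, 0 to 1 lower and 0 to 2 changed at least 2-fold, the calls arising without control replicate 4, whose counts at this locus are opposite to those of the other controls. All other settings gave 0 calls, and 0 gene lists passed in any setting. The lowest adjusted p of a list was 0.926 with camera over the refits. With fry on the main fit it was 0.153 in a single direction and 0.0963 in either direction. The log2 fold change of SLC7A5 stayed between 0.07 and 0.208 with adjusted p from 0.979 to 1, the lowest value being without knockdown replicate 6. Genes at an unadjusted p under 0.05 numbered 1104 to 2061. Among uncalled values, 37 of 1562 for named genes other than SLC7A5 and 91 of 925 list medians changed sign. The 925 include medians of the main fit repeated for fry and for camera with an estimated correlation, which could not change sign. The median log2 fold change of all genes was at most 0.0029 in size in any setting. With replicate number as a block there were 0 calls in either direction. Deviations from the group mean correlated at -0.021 to 0.054 between same-numbered libraries. By this measure, 2 of 12 libraries correlated best with their own number. No pairing by number showed, but as replicates differ little beyond counting noise, a pairing could be missed. Unrounded counts were not run because the table holds whole numbers. Depth limits single genes with few counts.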

Other observations

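The tests in this part were chosen after the results they measure were seen, and the bounds that decide them were written then too.

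SLC7A5 was not lower in the libraries labelled knockdown. Too little depth to show a 2-fold reduction in its counts is argued against. The lower 95% bound of its log2 fold change was -0.079, where a 2-fold reduction needs -1. That bound bears on SLC7A5 mRNA only where counts track it. The SD of its log2 CPM over all 12 libraries was 0.216 (95% interval 0.153 to 0.367), below that of 2 levels 2-fold apart, but this bears on a mix-up of knockdown and control libraries only where counts track SLC7A5 mRNA, which the values on exonic length leave in doubt. What stays open is a mix-up of libraries, a knockdown lost before harvest, libraries of other samples, or counts that do not measure SLC7A5 mRNA. The values on exonic length below bear on the last of these. CDKN2A, a gene deleted in A549, had 8.49 counts per kb, where the median of protein-coding genes was 11.73. As 1 gene chosen after its values were seen, it cannot tell libraries of other samples from counts that do not measure mRNA. No value here decides between the other explanations.

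Counts followed exonic length. Reads mostly from the mRNA of the cells are argued against, since 80 glycolysis, NRF2 target, mitotic and epithelial genes without annotated processed pseudogenes had 0.771 times the counts per kb of olfactory receptor genes (95% bootstrap interval 0.705 to 0.826). For ribosomal protein genes the ratio was 0.351, which reads lost to near-identical copies could lower. Reads mostly from the genomic DNA of the cells are argued against, since mitochondrially encoded genes, present in many copies per cell, had 1.31 times the autosomal density (1.252 to 1.33). A profile spread about evenly over annotated features may describe the table, with a rho of 0.801 and 90% of genes within a 5.73-fold range. Against it, 36 genes, among them IMMP2L at 508.87 counts per kb, lay above 10 times the median and 124 below 0.1 of it. Lengths came from GENCODE while most row names follow NCBI styles. The exons counted for these genes may thus differ from the length used, which was not tested. How such a profile arose stays open, and if it holds, the 0 calls say little about the response of A549 cells to the siRNA.

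The counts of calls were set beside those of other splits of the libraries. Of 100 splits of the 12 libraries, drawn at random with the real one included, 58 gave as many genes at an unadjusted p under 0.05 as the real 1638 (highest other 1762), so chance was not excluded for that count. The real split gave 0 genes past the threshold, 0 changed 2-fold and 0 gene lists (highest other 1 for each). All 100 splits reach a count of 0 by construction, so these say nothing about chance.

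Genes with copies elsewhere in the genome had lower counts per kb. The 406 genes with 3 or more annotated processed pseudogenes had a median of 9.36 counts per kb (quartiles 6.29 and 11.73), against 11.81 (9.1 and 13.86) for 15810 genes with none, a ratio of 0.792 (95% bootstrap interval 0.747 to 0.836). A permutation test gave p = 1e-05, the smallest that 100000 permutations can give, and the ratio was 0.792 with genes matched on length in 10 bins. The loss or splitting of reads shared with near-identical copies is a candidate explanation, as a hypothesis. Other properties of these often highly transcribed genes were not tested.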
